A study of Arabidopsis thaliana with 6 samples.

How the data were processed

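RNA-seq read counts were analysed for 6 libraries of wild-type Arabidopsis thaliana (Columbia) in 3 groups of 2: control, indole-3-acetic acid (IAA, the main natural auxin) at 1 nM, and melatonin (MT) at 10 nM. Per the labels' protocols, 4-day-old seedlings were moved to plates with either compound, both dissolved in ethanol, and 0.1% ethanol served as the control treatment. Samples were grouped by their titles, which place all 6 at 7 days. The 2 control columns of the deposited count table carry 72 h in their names, whereas their sample titles say 7 days. The age of the control plants is therefore open in every comparison against control, and the comparison of MT with IAA is unaffected. The sample labels name seedlings as the tissue, while the series' design text names rosette leaves, so the labels leave the organs in each library uncertain.

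The authors deposited 1 table of whole-number read counts per gene, with no normalization. The submitters' processing notes list Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq, with no role or order. The genome build, the annotation, the library kit and the use of strand in counting are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart. The table has 27978 rows, of which 27416 carry Arabidopsis locus codes and 562 are loci called newGene. Of the locus codes, 26719 matched the TAIR10.1 annotation, which was used only for gene names and for overlaps between genes.

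Total counts per library were 52929788 and 47351249 for control, 65558371 and 44424733 for IAA, and 48655999 and 40087221 for MT. A count of 3, taken as the floor for counting error, corresponds to 0.0458 to 0.0748 CPM (counts scaled to library size) in these libraries. Intervals and floors cover counting error only. No 2 libraries held identical counts. Within groups, the chi-square per degree of freedom over genes was 9.38 for control, 14.9 for IAA and 18.8 for MT, so the replicates differed by more than sampling noise and each was counted as a replicate. Libraries did not always lie closest to their own replicate. MT replicate 2 was at 12.6 with IAA replicate 1, 13.7 with IAA replicate 2 and 14.1 with control replicate 2. The Pearson correlation of log2 CPM was 0.9859 between the control libraries and 0.9864 between control replicate 2 and IAA replicate 1. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

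Genes were filtered with filterByExpr by group, leaving 21267 genes and removing 6711, and libraries were scaled by TMM factors. Differences were tested with edgeR 4.0.16 (R 4.3.3), using glmQLFit and glmQLFTest on the deposited counts with all 6 libraries in 1 fit, so that the 3 groups shared the estimate of the spread. The common biological coefficient of variation was 0.123, with 3 residual and 5.61 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, in 3 comparisons and in a test for any difference among the groups. Fold changes are given on the log2 scale with standard errors (SE), and levels as CPM with the SD of the 2 libraries. A fold against a group at 0 depends on the prior count and is not quoted.

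The 27 gene lists, with 494 members, were fixed before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists within each comparison. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It takes, per comparison, up to 10 genes with the largest increases and 10 with the largest decreases among those past the threshold, with separated groups and a mean of at least 1 CPM. It also takes up to 4 members past the threshold per list, or else the member with the lowest p as a value, and 9 genes of auxin response and melatonin synthesis or perception whatever their result. Not all of the genes chosen are described, and 1 of the 9 is not reported here.

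Because both treatments were compared with the same control libraries, chance agreement was estimated in 100 simulated data sets of 6 libraries with no difference between groups. Genes were drawn independently in these sets. Variation that many genes have in common was therefore absent, and the simulated ranges can be too narrow. Alternatives fixed in advance were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, other filters, removal of organelle genes, a replicate block, fits of only the groups compared, other thresholds, and leaving out each library.

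The test was tried on simulated data with 200 changed genes per treatment among 21267, in 5 draws. For IAA against control it called 43.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 90.6% of those changed 4-fold. For MT against control the shares were 41.8%, 71.6% and 86.1%. Unchanged genes made up 12.8% of the calls for IAA and 12.4% for MT, above the nominal 5%, although 4.8% of unchanged genes had a raw p under 0.05 in both. In a simulation with 1 list shifted 1.5-fold, camera with the preset correlation called that list and 1 of the 26 unshifted lists. With an estimated correlation the shifted list had an adjusted p of 0.064. That setting can therefore miss a real shift of this size, and the preset setting can call a list that did not move. Genes were drawn independently in these simulations, and the list was shifted in 1 draw. They do not show how often either setting errs for lists whose members vary together, such as the touch and rapid wounding list, with an estimated correlation of 0.745.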

Results

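Transcript levels were measured by RNA-seq in Arabidopsis seedlings kept for 7 days with IAA at 1 nM or MT at 10 nM, and in ethanol-treated controls, with 2 libraries per group. The series title gives the question as the promotion of root growth by melatonin and its dependence on IAA. Both compounds are small indole derivatives, and their doses differed, so the comparison between them is not at matched dose. Total counts ran from 40087221 to 65558371 per library. MT replicate 1 stood apart in its organelle reads. Plastid genes took 0.285% of its counts (95% Wilson interval for a binomial share 0.284 to 0.287), against 0.0196% to 0.0244% in the other 5 libraries. Control replicate 1 and MT replicate 1 lay at opposite ends of the first principal component, at -47.86 and 47.66, which held 38.2% of the variance.

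In seedlings given IAA, 8 of the 12 genes of the touch and rapid wounding list rose against control, whereas the salicylic acid and pathogen defence list did not pass (0 of 19 tested members called, camera adjusted p = 0.0799). DLAH (AT1G30370), a lipase of the DAD1-like acylhydrolase family, went from 0.599 ± 0.196 to 4.43 ± 0.471 CPM (SD, n = 2), and CML37, a calmodulin-like protein, went from 0.531 ± 0.263 to 3.46 ± 0.300 CPM (SD, n = 2). The transcription factor genes WRKY53, WRKY46 and ERF6 rose by log2 fold changes of 2.47 ± 0.24, 2.28 ± 0.22 and 2.37 ± 0.38 (SE). The largest fall among named genes was that of AT2G25510, at -1.44 ± 0.21 (SE), from 38.6 to 14.3 CPM. In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 149 of 21267 genes, 124 higher and 25 lower. The control columns of the count table are named 72 h and their samples 7 days, which bears on every value against control.

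The touch and rapid wounding list gave the lowest list p for IAA. All 12 of its members had positive fold changes, 8 rose past the threshold over all genes, and 11 did when adjusted over the list alone. The median log2 fold change was 1.62 (camera adjusted p = 4.56e-12, and adjusted p = 0.475 with an estimated correlation). WRKY33, a regulator of defence, rose from 28.2 to 102 CPM (log2 fold change 1.85 ± 0.15 SE, adjusted p = 0.00445, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). TCH3, a touch-induced calmodulin-like gene, rose by 1.28 ± 0.13, WRKY40 by 1.79 ± 0.19 and ZAT10 by 1.85 ± 0.27 (SE). Mean log2 CPM of the list was 2.26 and 3.09 in the control libraries, and 4.33 and 4.29 with IAA.

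Lists of hormone-related genes also differed between IAA and control. Whether they moved separately from the touch and rapid wounding list was not tested. In the jasmonate list, 4 of 18 tested members rose, and 7 rose and 1 fell when adjusted over the list alone. These included VSP2, a vegetative storage protein (log2 fold change 1.33 ± 0.10 SE), LOX2, a lipoxygenase of jasmonate synthesis (0.83 ± 0.08), the transcription factor MYC2 (0.98 ± 0.12) and the repressor JAZ1 (1.16 ± 0.18). The list had a camera adjusted p of 0.00235 (adjusted p = 0.475 with an estimated correlation). Of the 19 abscisic acid, cold and dehydration genes, 3 rose, and 7 did when adjusted over the list alone: the cold-response factors DREB1A (1.89 ± 0.29) and DREB1B (2.34 ± 0.37) and NCED3, a key enzyme of abscisic acid synthesis (1.13 ± 0.19), were those past the threshold over all genes. That list's adjusted p was 0.000108 (adjusted p = 0.475 with an estimated correlation). In the cytokinin list, ARR7, a type-A response regulator, rose by 0.77 ± 0.12, and 5 of 16 members rose when adjusted over the list alone (camera adjusted p = 0.000836, and adjusted p = 0.475 with an estimated correlation); without IAA replicate 2 the list did not pass (0.11).

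The auxin-response lists passed in the lower direction with IAA, without a single gene called over all genes. None of the 31 tested Aux/IAA and GH3 genes passed the threshold with IAA, over all genes or over the list alone, in edgeR's quasi-likelihood test. The list's median log2 fold change was -0.08 and its mean 0.06, of opposite sign, with a camera adjusted p of 0.0461 in the lower direction (adjusted p = 0.572 with an estimated correlation). That call ended with RLE factors (adjusted p = 0.0501) and without control replicate 1 (0.479), IAA replicate 1 (0.0696) or IAA replicate 2 (0.186). IAA19 changed by 0.05 ± 0.16, GH3.3 by -0.56 ± 0.18 and IAA29 by -0.02 ± 0.27 (log2, SE), none past the threshold. The SAUR list, small auxin-upregulated genes of cell expansion, had a median of -0.60 (camera adjusted p = 2.59e-09, and adjusted p = 0.475 with an estimated correlation). No SAUR gene passed over all genes, and 7 of 22 were lower when adjusted over the list alone. The auxin synthesis gene YUC2 changed by 0.23 ± 0.20, not past the threshold.

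The cell cycle, root meristem, root hair and cell wall lists were higher with IAA. In the cell cycle list, 26 of 27 members had positive fold changes with a median of 0.46 (camera adjusted p = 2.96e-09, and adjusted p = 0.475 with an estimated correlation). None passed over all genes and 10 did when adjusted over the list alone; CDC20.1, an activator of the anaphase-promoting complex, had the lowest p of the list, at 0.62 ± 0.12 (SE). The root meristem and lateral root list had a median of 0.49 (adjusted p = 0.0115, and adjusted p = 0.475 with an estimated correlation), with 0 of 15 members past the threshold. The root hair list had a median of 0.81 (adjusted p = 0.00135, and adjusted p = 0.603 with an estimated correlation), with 0 of 16 past it and 1 over the list alone. The root endodermis list did not pass (median 0.39, 0 of 11 members called, adjusted p = 0.12). Both are markers of root tissue, and the mean log2 CPM of the root hair list was -0.26 and 0.73 in the control libraries against 0.85 and 1.31 with IAA. Among expansins and XTH cell wall enzymes, XTH22, which rose by 1.08 ± 0.10, was the only 1 of 22 members past the threshold over all genes. Over the list alone 8 rose and 1 fell, and the list had a camera adjusted p of 0.00576 (adjusted p = 0.475 with an estimated correlation). The calls of the root meristem and root hair lists ended without control replicate 1 (adjusted p = 0.193 and 0.216), without IAA replicate 2 (0.268 and 0.0551) and with a filter at 5 CPM (0.0547 and 0.109), and that of the cell wall list without IAA replicate 1 (0.0696).

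The iron and glucosinolate lists were lower with IAA. The iron deficiency list had a median of -0.29 (camera adjusted p = 0.012, and adjusted p = 0.475 with an estimated correlation), with 0 of 13 members past the threshold and 3 lower over the list alone. The glucosinolate list had a median of -0.22 (adjusted p = 0.00567, and adjusted p = 0.603 with an estimated correlation), although its single called member, MYB51, a regulator of indole glucosinolates, rose by 0.94 ± 0.13. The iron call ended without control replicate 2 (adjusted p = 0.238) and with a filter at 5 CPM (0.233), and the glucosinolate call without control replicate 1 (0.105) or IAA replicate 1 (0.149). The nitrate reductase gene NIA1 fell by 0.45 and the anthocyanin repressor gene MYBL2 fell by 0.42 on the log2 scale. The number of called genes depended on single libraries: it was 17 without control replicate 1, 48 without IAA replicate 1, 21 without IAA replicate 2 and 84 without MT replicate 2. Leaving out a library also leaves less to measure the spread, so part of these falls may be lost power, which was not tested. DESeq2 called 475, 268 genes were called with no filter on low counts, and fitting only these 2 groups gave 81.

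**Figure D1:**
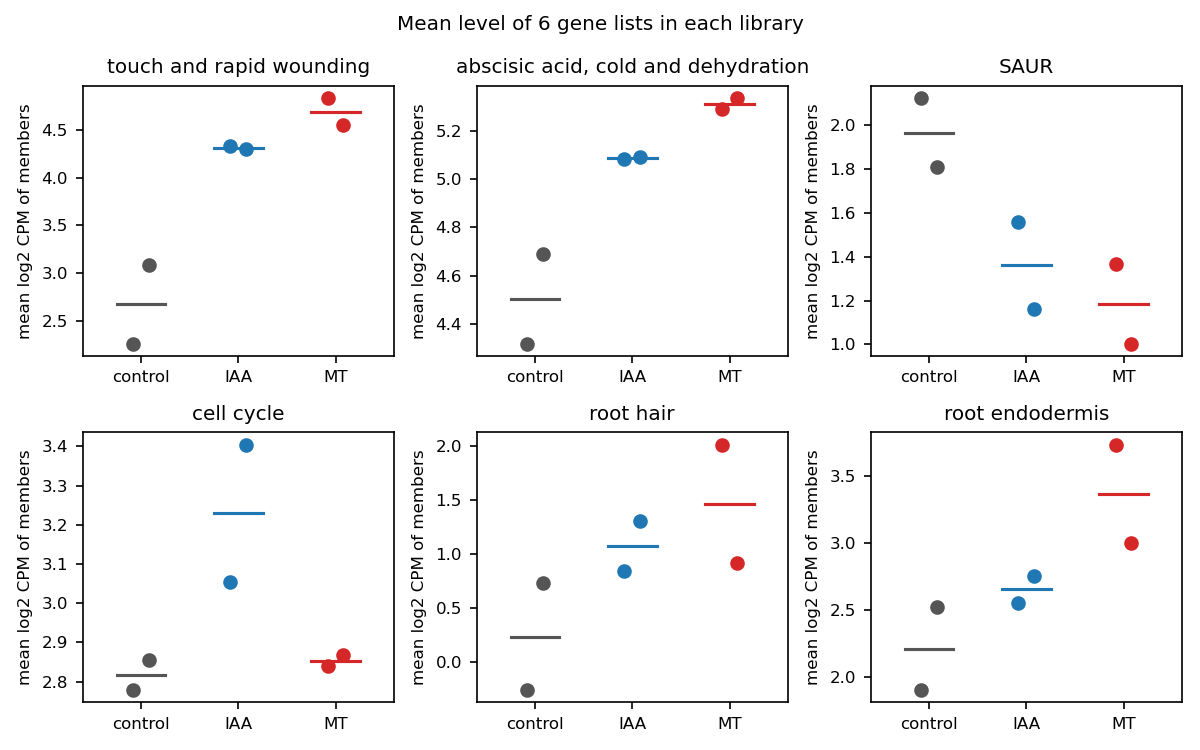
Mean log2 CPM over the members of 6 gene lists, with 1 point per library and a bar at each group's mean. The touch and rapid wounding list was at 2.26 and 3.09 in control and at 4.29 to 4.83 in the treated libraries, and the root endodermis list was highest in MT replicate 1, at 3.73.

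In seedlings given MT, 11 of the 12 touch and rapid wounding genes and 7 of the 19 abscisic acid, cold and dehydration genes rose against control. DLAH rose from 0.599 to 8.06 ± 2.27 CPM (SD, n = 2; log2 fold change 3.76 ± 0.31 SE) and WRKY53 by 3.43 ± 0.24, while MYB15, a transcription factor gene, rose by 3.29 ± 0.32. The largest falls among named genes were those of AT5G60548 (-1.70 ± 0.19), the auxin-responsive SAUR21 (-1.38 ± 0.28) and AT3G18773 (-1.18 ± 0.14). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 403 genes, 355 higher and 48 lower, of which 200 changed at least 2-fold. The control columns named 72 h bear on these values too.

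In the touch and rapid wounding list 11 of 12 members rose with MT, and the median log2 fold change was 1.96 (camera adjusted p = 2.73e-13, and adjusted p = 0.605 with an estimated correlation). WRKY33 rose from 28.2 to 162 CPM (log2 fold change 2.52 ± 0.15 SE), TCH3 by 1.91 ± 0.13, WRKY40 by 2.16 ± 0.19 and the calmodulin-like gene CML24 by 1.16 ± 0.13. Among the 19 abscisic acid, cold and dehydration genes 7 rose, and 12 did when adjusted over the list alone. DREB1B rose by 3.04 ± 0.37, DREB1A by 2.39 ± 0.29, DREB1C by 2.53 ± 0.36 and NCED3 by 1.5 ± 0.19 (list adjusted p = 5.40e-06, and adjusted p = 0.605 with an estimated correlation). In the cytokinin list the type-A regulators ARR7, ARR5 and ARR6 rose by 1.05 ± 0.12, 0.74 ± 0.12 and 0.80 ± 0.15 (list adjusted p = 0.00206, and adjusted p = 0.605 with an estimated correlation).

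Salicylic acid, redox and jasmonate genes were called singly with MT. The defence regulators CBP60G, PAD4, WRKY70 and SARD1 rose by 1.42 ± 0.18, 0.94 ± 0.13, 0.85 ± 0.14 and 1.60 ± 0.29 (log2, SE), 4 of 19 tested members, and their list did not pass (camera adjusted p = 0.0613). Of the 18 redox genes 3 rose and 2 fell. The kinase gene OXI1 rose by 2.83 ± 0.32 and the NADPH oxidase gene RBOHD by 0.47 ± 0.06, and the superoxide dismutase genes CSD2 and CSD1 fell by 0.55 and 0.41 (list adjusted p = 0.491). MYC2, JAZ1 and JAZ5 rose by 1.16 ± 0.12, 1.39 ± 0.18 and 1.62 ± 0.31, 3 of 18 jasmonate genes (list adjusted p = 0.245).

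The root endodermis, root hair and cell wall lists were higher with MT, with 2 of 11, 1 of 16 and 4 of 22 members past the threshold over all genes, and the root meristem and lateral root list did not pass (0 of 15 called, camera adjusted p = 0.152). All 11 root endodermis genes and all 16 root hair genes had positive fold changes, with medians of 1.17 in both lists. Both lists are markers of root tissue. Mean log2 CPM of the endodermis list was 1.90 and 2.52 in control, 2.55 and 2.76 with IAA, and 3.73 and 3.00 with MT. Root markers were thus read in every library, which argues against rosette leaves alone as the tissue. The share of root in each library stays unknown. The photosynthesis list leaned the other way, with 8 of 30 members above 0 and a median of -0.058 (camera adjusted p = 0.0796). A different share of root in the libraries was not tested for the comparisons against control, and it cannot be told apart here from a response of these genes. CASP1, a protein of the Casparian strip, rose by 1.95 ± 0.39, the peroxidase gene PER72 by 1.28 ± 0.19, and LRX1, a root hair cell wall protein, by 1.47 ± 0.29. Over the list alone, 10 endodermis and 7 root hair genes passed (camera adjusted p = 4.68e-06 and 8.59e-06, and adjusted p = 0.605 and 0.624 with an estimated correlation). Both lists were highest in MT replicate 1, the library with the high plastid share: the root hair list was at 2.02 there and at 0.92 in MT replicate 2, and without MT replicate 1 the adjusted p was 0.00623 for root hair and 0.000702 for endodermis genes. Among expansins and XTH enzymes, XTH22, XTH18, XTH23 and EXPA17 rose by 1.42 ± 0.10, 1.80 ± 0.29, 1.43 ± 0.23 and 2.70 ± 0.53 (list adjusted p = 0.000878, and adjusted p = 0.605 with an estimated correlation).

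Auxin and melatonin genes were mostly not called with MT. None of 31 Aux/IAA and GH3 genes and none of 7 melatonin synthesis and receptor genes passed the threshold in edgeR's quasi-likelihood test. YUC3, an enzyme of auxin synthesis, rose from 0.629 to 2.27 CPM (1.85 ± 0.37). In the SAUR list, SAUR68, SAUR63 and SAUR21 fell by 1.00, 0.99 and 1.38, 10 of 22 were lower when adjusted over the list alone, and the median was -0.78 (adjusted p = 6.75e-12, and adjusted p = 0.605 with an estimated correlation). The melatonin genes NSI (a serotonin N-acetyltransferase gene), ASMT and OMT1 changed by -0.18 ± 0.08, 0.23 ± 0.20 and -0.07 ± 0.07, and CAND2, a proposed melatonin receptor, by -0.01 ± 0.10; ASMT was at 0.547 without MT replicate 2, where it passed (adjusted p = 0.0392), and at -0.21 without MT replicate 1, where it did not (0.728). IAA19 changed by 0.01 ± 0.17 and GH3.3 by -0.56 ± 0.18. The glucosinolate list had a median of -0.40 (adjusted p = 0.00115, and adjusted p = 0.624 with an estimated correlation); CYP83A1, of aliphatic glucosinolate synthesis, fell by 0.39, whereas MYB51 and CYP81F2, of the indole branch, rose by 1.72 ± 0.13 and 1.46 ± 0.27. Without control replicate 1 the number of called genes was 112 and without MT replicate 1 it was 172, and DESeq2 called 823.

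**Figure D2:**
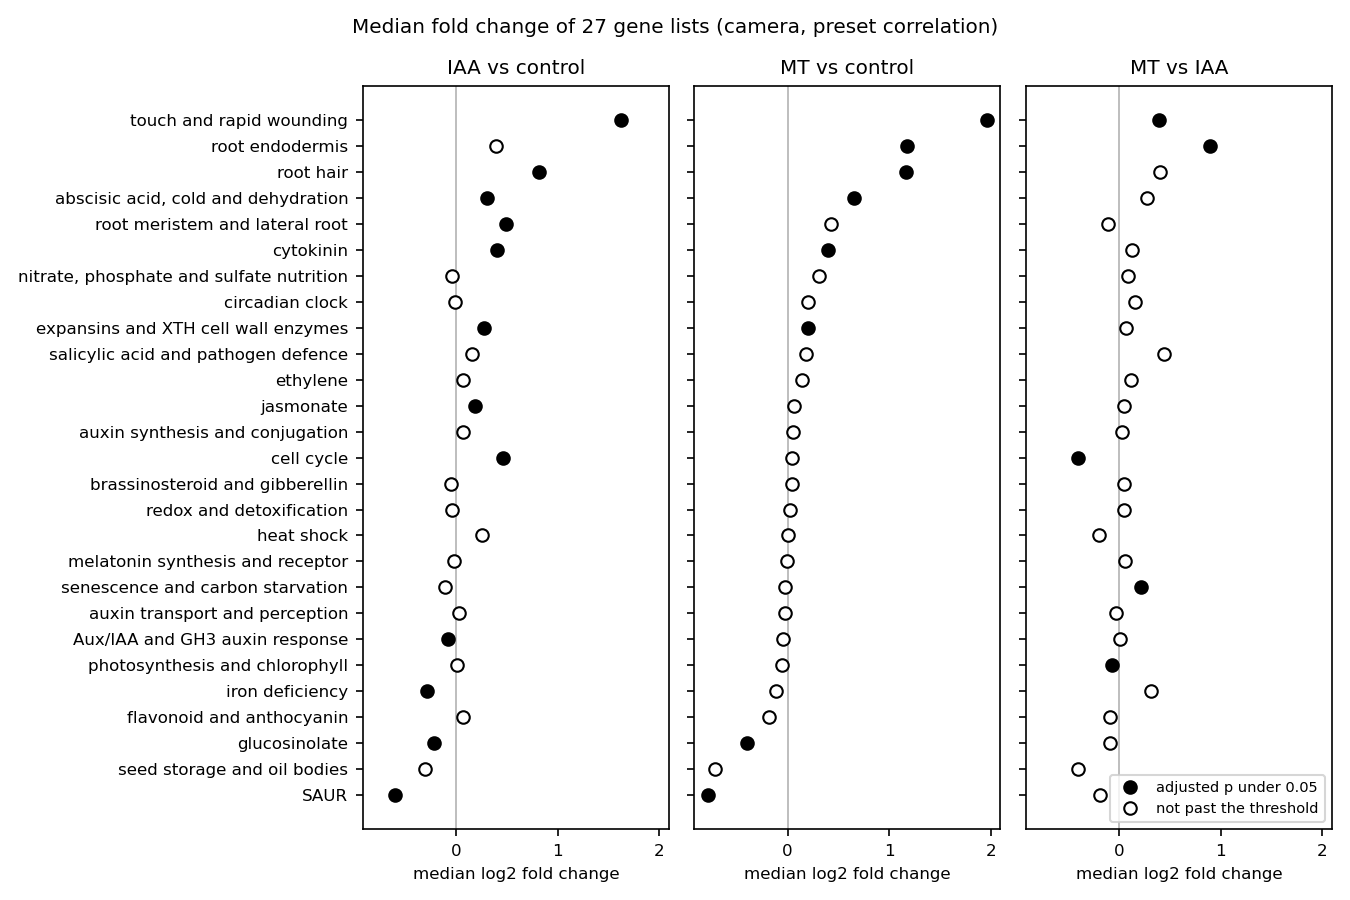
Median log2 fold change of each of the 27 gene lists in the 3 comparisons, filled where the camera adjusted p with the preset correlation was under 0.05. The SAUR list lies at -0.60 with IAA and -0.78 with MT, and the touch and rapid wounding list at 1.62 and 1.96; no list passed with an estimated correlation.

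MT and IAA, at their different doses, differed from each other in few single genes. MPK3, a mitogen-activated protein kinase of immune signalling, was at 146 CPM with MT and 89.9 CPM with IAA, a log2 difference of 0.70 ± 0.06 (SE). VSP2 was lower with MT than with IAA by 1.52 (12.9 against 37.0 CPM), AT1G52000 by 1.23 and TGG2, a myrosinase that hydrolyses glucosinolates, by 0.78. In control VSP2 was at 14.8 CPM and MPK3 at 74.6 CPM. TGG2 was at 246 CPM in control, 254 with MT and 435 with IAA. AT1G52000 was at 17.7 CPM in control, 11.9 with MT and 27.8 with IAA. These 4 genes were those that edgeR's quasi-likelihood test called, with adjusted p of 0.00735 for MPK3, 0.00423 for VSP2, 0.00912 for AT1G52000 and 0.00546 for TGG2 after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2235 genes, and DESeq2 called 255.

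With the preset correlation 5 of the 27 gene lists differed between MT and IAA, and 0 did with an estimated correlation. The cell cycle list was lower with MT than with IAA, with a median of -0.41 and 2 of 27 members above 0 (camera adjusted p = 9.51e-09, and adjusted p = 0.682 with an estimated correlation). Its mean log2 CPM was 3.05 and 3.4 in the IAA libraries against 2.84 and 2.87 with MT, and 2.78 and 2.85 in control. With MT against control the list did not pass (median 0.04, 16 of 27 members above 0, camera adjusted p = 0.808). The difference thus lay in higher levels with IAA, not in a fall below control with MT. The root endodermis list was higher with MT (median 0.90, 11 of 11 members above 0, adjusted p = 0.000444, and adjusted p = 0.682 with an estimated correlation), and the touch and rapid wounding list was higher by a median of 0.39 (adjusted p = 0.0136, and adjusted p = 0.682 with an estimated correlation). The senescence and carbon starvation list was higher (0.22, adjusted p = 0.0334) and the photosynthesis list lower (-0.07, adjusted p = 0.0014), both with adjusted p = 0.682 with an estimated correlation. Without MT replicate 1 the endodermis, touch, senescence and photosynthesis lists had adjusted p of 0.101, 0.122, 0.116 and 0.119, and the cell cycle list 2.70e-06; without IAA replicate 2 the senescence list had 0.174.

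For auxin and melatonin genes the intervals of the difference between MT and IAA were as follows. On the log2 scale the 95% interval was -0.42 to 0.33 for IAA19, -0.41 to 0.41 for GH3.3, -0.73 to 0.50 for IAA29 and -0.14 to 0.29 for CAND2. The median half-width of this interval over all 21267 genes was 0.28, so differences smaller than that were often not resolved. The intervals are not adjusted for the number of genes, and larger differences could also miss the adjusted threshold, as MYB51 did at 0.78. WRKY33 and TCH3 had intervals of 0.35 to 0.98 and 0.34 to 0.91 and did not pass after adjustment, although TCH3 did with DESeq2 (adjusted p = 0.00144). Without IAA replicate 1 the number of called genes was 0 with 2432 at an unadjusted p under 0.05, without IAA replicate 2 it was 7, and without MT replicate 2 it was 55.

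Fold changes of IAA and MT against control were compared across genes. Of the genes called in each, 108 were higher in both, WRKY33, DLAH and MYB51 among them, and 8 were lower in both, AT3G18773 among them. A single gene, AT1G52000, was called in opposite directions, at 0.65 ± 0.11 with IAA and -0.57 ± 0.11 with MT (log2, SE). Simulated libraries without any effect gave 0.4 and 0.25 such genes on average, and independent lists of these sizes would share 2.07 and 0.0564. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.667 against a simulated mean of 0.497, and the covariance was 0.166 against 0.0496. The share of genes with the same sign was 68.2%, against a simulated mean of 66.6% and a simulated range of 65.7% to 67.4%. Both comparisons used the same 2 control libraries, which were not split, so part or all of the excess may come from the shared controls. The simulated sets gave control and treated libraries the same mean level for each gene. They therefore do not cover controls that differed from both treatments in age or handling. A test for any difference among the 3 groups called 282 genes, of which 141 were also called with IAA and 256 with MT. By the sign of the fold change alone, called or not, 243 of the 282 lay above control in both treatments, 32 below in both and 7 in opposite directions. Without control replicate 1 the shared genes numbered 15, without IAA replicate 1 35, without IAA replicate 2 12, without MT replicate 1 64 and without MT replicate 2 62, and the genes called in any group were 79 without control replicate 1, 167 without control replicate 2 and 130 without MT replicate 1.

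**Figure D3:**
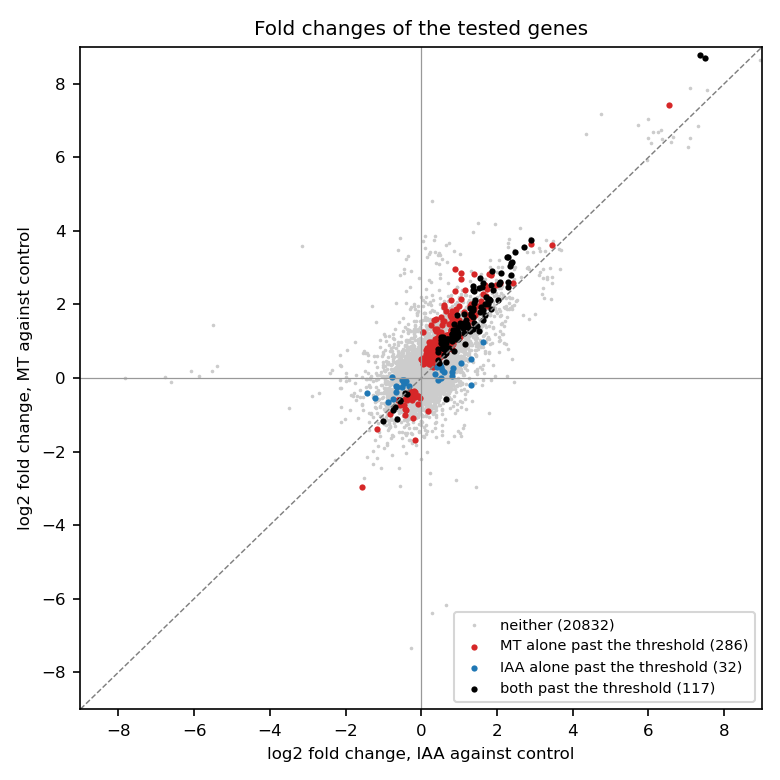
Log2 fold change against control with MT (vertical) and IAA (horizontal), 1 point per tested gene, coloured by which comparison passed an adjusted p of 0.05; the dashed line marks equal change. Most genes past the threshold in both lie in the upper right, where 108 genes were higher in both treatments.

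Some named genes overlap another annotated gene, and without a stated strand their counts are uncertain. These include WRKY53, WRKY33, TCH3, WRKY40, MYC2, DREB1A, CASP1, CML24, ARR6, SAUR63, CSD1, SARD1, MPK3, NSI, CAND2 and AT3G18773. SAUR21 and its neighbours, and DREB1A, DREB1B and DREB1C, are members of gene families with similar sequences, between which reads could be split.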

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

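The tests of poly(A)-free RNA and of melatonin for the organelle reads were chosen only after the result was seen; the others were written before any list was tested, but after the leading genes of each comparison, from which the touch and jasmonate patterns come, and the organelle shares had been seen. How the clock test was read, and the intervals used for the organelle tests and for the touch and photosynthesis lists, were settled after their values were known.

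A direct test of MT against IAA, in which the control levels carry no weight, found a difference in 4 genes and 5 gene lists. The log2 differences were -1.52 for VSP2, -0.78 for TGG2, 0.70 for MPK3 and -1.23 for AT1G52000. Median log2 differences were -0.41 for the cell cycle list, 0.895 for root endodermis, -0.067 for photosynthesis and chlorophyll, 0.39 for touch and rapid wounding and 0.219 for senescence and carbon starvation. These list calls rest on the preset correlation: with an estimated correlation each had an adjusted p of 0.682. Without MT replicate 1 the adjusted p was 0.101 for endodermis, 0.122 for touch, 0.116 for senescence and 0.119 for photosynthesis, and without IAA replicate 2 it was 0.174 for senescence.

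The touch and rapid wounding list was higher in both treatments than in control, with 8 of 12 members called with IAA and 11 with MT, and no technical explanation tested was excluded. Handling that differed between libraries stays open: the largest difference within a group, 0.83 between the control libraries, was 0.506 of the smaller treated-minus-control difference, just above the bound of 0.5 set to exclude it. Handling was tested on this list alone, so it stays open, untested, for the other lists that were higher in both treatments. An age difference of the control plants, as the 72 h column name would mean, would leave MT and IAA alike if it were the whole cause; the MT libraries lay above the IAA libraries in all 4 pairs, by 0.218 to 0.535, and the 95% interval over the pairs, 0.12 to 0.64, met the bound set against it, but that bound was a poor choice, since the pairs share libraries. Over the 2 libraries of each group the interval was -0.23 to 0.98, and a test with an estimated correlation gave p = 0.362, so this stays open, and age markers decide nothing, since their miss (median 0.15 with IAA and -0.041 with MT, higher p = 0.615) could also mean a change too small to see in whole seedlings. A different time of harvest cannot be told apart from treatment either: morning minus evening clock genes differed between MT and control by 1.544 times the largest difference within a group, but between IAA and control by 0.044 against 0.167, and a response to IAA or melatonin itself is also open, untested.

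Plastid and mitochondrial reads were high in MT replicate 1 alone. Melatonin as the cause is argued against by MT replicate 2, whose plastid share of 0.0222% lay within the range of the control and IAA libraries. Carry-over of RNA without a poly(A) tail stays open: 76.8% of organelle genes were highest in that library (95% exact interval 69.6 to 83.1), a range that includes the bound of 80% set for it. The share was 97.6% for plastid and 54.4% for mitochondrial genes. Median ratios to the other libraries were 5.93 and 1.83, although carry-over was taken to raise both genomes alike. The interval takes genes as independent, which organelle genes of the same library need not be. Genomic DNA stays open too: nuclear genes seen in that library alone, scaled by its total count, were 0.976 times the highest value elsewhere (95% interval 0.76 to 1.25).

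Jasmonate-associated genes lower with MT than with IAA were a pattern noticed in single genes such as VSP2. In the jasmonate list 10 of 18 tested members lay above 0 (median 0.05), and the list as a whole did not pass (camera adjusted p = 0.255). The test for 1 IAA library as the source, with a higher raw p of 0.314 without either library, therefore decides nothing. For a different share of shoot and root, the lists moved in the directions set in advance for it. Photosynthesis was lower with MT (median -0.067), and root hair (median 0.403, 15 of 16 members above 0) and root endodermis (0.895, 11 of 11) were higher. Raw p was 0.000156, 0.0477 and 3.29e-05 in limma's camera with the preset correlation (adjusted p = 0.0014, 0.107 and 0.000444). With an estimated correlation camera gave raw p of 0.294, 0.594 and 0.204. A difference in share therefore stays open. The mean of the photosynthesis list over libraries differed by -0.086 (95% interval -0.24 to 0.06). The 3 jasmonate genes lower over the list alone, VSP2, VSP1 and LOX2, had intervals of -1.75 to -1.28, -1.58 to -0.35 and -0.74 to -0.36, all below it. These genes were chosen because they were lower in these same data. That a lower shoot share would lower all shoot transcripts alike was assumed, not tested. The gap therefore does not decide against a difference in share. A response to the treatments is open, untested.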

How the results depend on the processing

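Scaling by RLE, upper-quartile factors or library totals, limma-voom, a mean filter of 5 CPM and removal of organelle genes left the 4 counts of called genes within 1.5 times of 149 (IAA), 403 (MT), 4 (MT against IAA) and 282 (any group). DESeq2 called 475, 823, 255 and 941 genes and 284 shared genes; with no filter on low counts there were 268 for IAA, 13 for MT against IAA, 543 for any group and 186 shared, and the correlation was 0.532. At an adjusted p under 0.1 the counts were 276, 627, 7 and 491, with 192 shared, and at 2-fold or more 75, 200, 2 and 150, with 68 shared. Fitting only IAA and control gave 81, where fewer samples carry the spread. The cause of the other changes was not tested.

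Leaving out each library in turn gave 17 to 109 genes for IAA, 112 to 447 for MT, 0 to 55 for MT against IAA, 79 to 284 for any group and 12 to 96 shared genes, and correlations of 0.47 to 0.819. A group left with 1 library was assumed to vary like the others. Fewer libraries also give less power, which was not separated from the weight of the library left out. Lists past the threshold numbered 9 to 14 of 27 for IAA, 8 to 12 for MT and 4 to 9 for MT against IAA. Over the left-out libraries, RLE factors, the 5 CPM filter and the replicate block, 5 of the 12 lists for IAA, 8 of 8 for MT and 1 of 5 for MT against IAA kept their call throughout. With an estimated correlation, and with fry, 0 lists passed in each comparison (0 for IAA, 0 for MT, 0 for MT against IAA), and with the 5 CPM filter 9 passed for MT against IAA.

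Replicate numbers are shared only as numbers: deviations of same-numbered libraries correlated at 0.033 between control and IAA, -0.149 between control and MT and 0.012 between IAA and MT. With the replicate block 137 genes were called for IAA, 351 for MT, 5 for MT against IAA and 255 for any group, and 8 lists passed for MT against IAA.

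Of 95 named results past the threshold, 27 kept their call under every alternative run for them and 68 lost it under at least 1, 61 of the 95 without control replicate 1. The 5 CPM filter was run for 74 of the 95, and none of the 95 turned direction under the alternatives run. Among 79 named values not past the threshold, 32 alternative values for 14 of them changed sign, 25 on leaving out a library, and 0 of these 32 passed the threshold. With the sign kept, 27 of the 79 passed under at least 1 alternative: 25 with DESeq2, 7 with no filter, 2 with the replicate block, and 1 each without control replicate 2, MT replicate 1 and MT replicate 2. For IAA against control, IAA29 was 0.034 with limma-voom and 0.002 with the replicate block. For MT against control, IAA19 was -0.006 with no filter and with the replicate block, and YUC2 -0.005 with no filter. For MT against IAA, GH3.3 was 0 with no filter and -0.002 with the replicate block. Leaving out each library, log2 fold changes with IAA ran from -0.065 to 0.144 for IAA19, -0.374 to 0.433 for IAA29 and -1.619 to 0.279 for CRA1. With MT they ran from -0.213 to 0.179 for IAA19, -0.491 to 0.317 for IAA29, -0.205 to 0.231 for YUC2, -0.21 to 0.547 for ASMT and -0.058 to 0.024 for CAND2. For MT against IAA they ran from -0.267 to 0.137 for IAA19, -0.228 to 0.205 for GH3.3, -0.3 to 0.051 for IAA29, -0.075 to 0.114 for NSI, -0.29 to 0.479 for ASMT and -1.305 to 0.601 for CRA1.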

Other observations

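A further 9 gene lists did not pass the preset threshold in either treatment, which does not show that they were unchanged. With MT, the adjusted p of camera was 0.106 for flavonoid and anthocyanin genes, 0.103 for nitrate, phosphate and sulfate nutrition, 0.128 for the circadian clock, 0.808 for heat shock, 0.0613 for ethylene, 0.937 for brassinosteroid and gibberellin, 0.301 for auxin synthesis and conjugation, 0.496 for auxin transport and perception, and 0.241 for seed storage and oil bodies, of which 2 members could be tested. With IAA the same lists had 0.828, 0.846, 0.828, 0.0995, 0.477, 0.477, 0.149, 0.846 and 0.477. Single members did pass, among them YUC3 with MT, NIA1 with IAA and MYBL2 in both. In the flavonoid list, 6 of 20 genes were lower and 2 higher with MT when adjusted over the list alone. ACS6, an ethylene synthesis enzyme, rose in both treatments, by 1.39 ± 0.19 with IAA and 1.5 ± 0.19 with MT (log2, SE).

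Age markers gave no calls: 7 of 9 SPL and floral-transition genes lay above 0 with IAA and 4 of 9 with MT. Among the 149 IAA calls, 78.5% were also called with MT, 116 in the same direction and 1 in the opposite one. MT calls were 403 of all 21267 genes, and both comparisons used the same control libraries.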
